A study of Homo sapiens with 6 samples.

How the data were processed

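RNA was sequenced from IMR32 cells, an established human neuroblastoma cell line with an amplified MYCN gene, after 24 h with DMSO or with 20 µM sAKZ692, a small molecule known from the labels by its code name. There were 6 libraries, 3 per group. The groups were taken from the treatment labels and the replicate numbers from the sample titles. Per the labels' protocols, total RNA was prepared with an RNeasy kit and sequenced on a BGISEQ-500 as single-end reads of 50 bases at a stated depth of 20000000 reads per library. Per the submitters' processing notes, kallisto was used. Its version, the transcript annotation, the genome build and the use of strand are not given in the sources used here.

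The authors deposited 1 table of TPM, a transcript abundance corrected for transcript length and scaled to the same total in each library, with 1 row per gene symbol and 1 column per library. All 6 columns matched a sample title. The table held 11351 gene symbols, none repeated and none at 0. The listed genes summed to 65.9% of the full TPM scale in replicate 3 of sAKZ692 and to between 61.2% and 61.9% in the other libraries. Genes outside the table were not analysed here. TPM keeps no trace of the number of reads, so the depth of each library is unknown, and no counting interval or detection floor was computed.

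Genes with a mean of at least 1 TPM over the 6 libraries were tested, which left 9137. Values were transformed to log2(TPM + 1). A fold change on this scale understates the change of genes near or below 1 TPM, so mean TPM or ratios of mean TPM are given beside the largest rises. Groups were compared with limma 3.58.1 in R 4.3.3 using a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Counts at an absolute log2 fold change of at least 1 are given as well. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which can be technical.

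Before the data were examined, 27 gene lists were fixed: NRF2 targets, pentose phosphate and NADPH, iron and haem, glyoxalase and aldehyde clearance, glycolysis, glucose-responsive MondoA targets, HIF targets outside glycolysis, ATF4 and integrated stress response, ER unfolded protein response, heat shock response, metallothioneins, AhR targets, cholesterol biosynthesis, fatty acid synthesis, DNA replication, mitosis, p53 targets, noradrenergic neuroblastoma markers, neurofilament and synaptic genes, mesenchymal and stromal markers, Schwann and glial markers, immediate early genes, NF-kB targets, interferon-stimulated genes, mitochondrially encoded genes, nuclear respiratory chain genes and cytosolic ribosomal proteins. Of 523 listed genes, 332 were in the table. Lists with at least 5 tested members, 20 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over these 20. Camera compares a list with the other genes tested. It was repeated with a correlation estimated from the data, and with limma's fry, which tests whether a list's genes move on balance one way. Members were counted over all genes tested and adjusted over the list alone. The lists share few tested members, among them TKT in the NRF2 and pentose phosphate lists, FTH1 and BLVRB in the NRF2 and iron lists, and SLC7A11 in the NRF2 and ATF4 lists.

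The genes named were chosen by a rule also fixed before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap. It added up to 4 members of each list with the smallest adjusted p or, where none passed, up to 2 with the highest mean TPM. It then added the 2 genes with the highest mean TPM and 19 genes fixed by name, of which 10 were in the table and the other 9, among them KEAP1, NFE2L2 and HMOX1, were not analysed here. The rule gave 104 genes, and the results of some of these, and of the Schwann and glial list, are not reported here. Genes named outside it are said to be chosen after their values were seen.

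The limma step was tested on simulated values for the 9137 genes of the comparison of sAKZ692 with DMSO, with 200 genes changed. It recovered 41.8% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 13 false calls among 156, and made 0 calls at the adjusted threshold when no gene was changed. The simulated noise was independent between genes and equally wide in both groups, and the changes were set on log2(TPM + 1). The real data hold an outlying treated library, so these rates need not apply to them.

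Alternatives chosen before the data were examined were a pseudocount of 0.1 or 0.5, no filter or a minimum mean of 5 TPM, scaling each library by its median ratio to the gene-wise geometric mean, quantile normalization, limma without the trend or with robust estimation, a replicate block, and leaving out each library in turn. Limma array weights and a restriction to protein-coding genes were added after the data had been seen. A count-based test was not run, because the values are not counts. GENCODE release 29 was used only for gene type and transcript length by symbol, matching 9059 of the 9137 tested genes, of which 8598 were protein coding. Positions are not given, since the build is not given in the sources used here.

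Kallisto assigns reads by their match to transcripts, so genes with near-identical copies, such as the ribosomal protein genes with their processed pseudogenes, the GAGE family and the pseudogene HMGN1P26, can share reads and their levels are uncertain.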

Results

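The transcriptome of IMR32 neuroblastoma cells was measured by RNA sequencing after 24 h with 20 µM sAKZ692, a small-molecule activator of the transcription factor NRF2 according to the study's design text, or with the solvent DMSO. Each group had 3 libraries. Values are TPM for 11351 genes, of which 9137 reached a mean of 1 TPM and were tested. The comparison asked which transcripts differ between compound and solvent, and the study's title sets it in the context of NRF2 signaling and glycolysis. The depth reached by each library is unknown, because TPM does not carry read counts.

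With sAKZ692, SLC7A11, the cystine transporter subunit, rose from 0.532 ± 0.0709 to 9.87 ± 3.94 TPM (SD, n = 3), a log2 fold change of 2.76 and a ratio of mean TPM of 18.5. SCG2, which encodes the neuroendocrine granule protein secretogranin II, rose from 21.1 ± 1.53 to 135 ± 22.9 TPM, and DUSP6, a phosphatase that inactivates ERK, from 4.37 ± 0.545 to 27.8 ± 10.5 TPM. TTC39A, LGALS3BP, JUP (plakoglobin), HES7, the stress-response transcription factor ATF5, STUM and SGPP2 also rose, with log2 fold changes between 2.21 and 2.63 and ratios of mean TPM between 5.75 for ATF5 and 19.6 for HES7. The ratio for HES7 is uncertain, since its DMSO libraries were at 0.454, 0.0426 and 0.431 TPM. Replicate 3 of sAKZ692 differed from replicates 1 and 2 for LGALS3BP (58.3, 45.5 and 126 TPM in replicates 1, 2 and 3), JUP (18.7, 17.2 and 39.0 TPM) and HES7 (7.79, 7.17 and 3.17 TPM). In the opposite direction, the chemokine gene CXCL12 fell from 17.3 ± 2.38 to 4.57 ± 1.04 TPM (SD, n = 3), the Wnt receptor gene FZD8 from 26.1 ± 0.738 to 7.45 ± 0.684 TPM, RASL11B from 49.8 ± 1.13 to 17.7 ± 3.47 TPM, and LDHA, the lactate dehydrogenase subunit of glycolysis, from 1410 ± 54.7 to 597 ± 45.3 TPM. CDC6 and MCM4, members of the DNA replication list, and DTL and CHAF1A, which are in no fixed list, were also among the 12 largest falls, falling by between 1.11 and 1.23 on the log2 scale. HMGN1P26, a processed pseudogene, fell from 3.13 ± 0.412 to 0.931 ± 0.409 TPM, and its level is uncertain.

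PRPH, which encodes the intermediate filament peripherin, and CHAC1, a glutathione-degrading enzyme, were also among the 12 largest rises, but their size depended on replicate 3 of sAKZ692. PRPH was at 33.0, 26.7 and 179 TPM in the 3 treated libraries against 8.05 ± 0.0482 TPM with DMSO, and CHAC1 was at 45.7, 50.6 and 9.88 TPM against 5.34 ± 0.896 TPM. Without replicate 3 their log2 fold changes were 1.76 and 2.96, against 2.61 and 2.24 with it. The transcription factor gene ATOH8 and the Notch-modifying glycosyltransferase gene LFNG, both among the largest falls, had log2 fold changes of -1.18 and -1.13, and of -0.71 and -0.75 without replicate 3. All 4 calls were lost when any 1 DMSO library was left out, with adjusted p between 0.0559 and 0.107, and that of CHAC1 also without replicate 1 or 2 of sAKZ692, with adjusted p of 0.0527 and 0.0511. That of ATOH8 was also lost after quantile normalization (adjusted p = 0.060) and in limma without the trend (adjusted p = 0.051).

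In all, 2204 genes were higher and 777 lower with sAKZ692 at the adjusted p threshold of 0.05 in limma. Of these, 392 were higher and 23 lower by at least 1 on the log2 scale. The groups did not overlap in 50.5% of the tested genes, where chance gives 10%. The median log2 fold change over all tested genes was 0.14, so that a gene at 0 lay below the median gene. The split between higher and lower genes depended on the scaling. Dividing each library by its median ratio moved that median to -0.03, and gave 1242 higher and 1754 lower genes, and quantile normalization gave 1077 and 1184. The share of higher genes among the calls was 73.9% as deposited, 41.5% after median-ratio scaling and 47.6% after quantile normalization. Without any 1 of the DMSO libraries 1260, 1215 and 1213 genes were higher and 406, 404 and 443 lower.

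Replicate 3 of sAKZ692 stood apart from the other libraries. On log2(TPM + 1), across the tested genes, which are not independent replicates, it correlated with replicates 1 and 2 at Pearson's r = 0.971 and 0.972, while those correlated with each other at 0.992 and the DMSO libraries at 0.994 to 0.995. The DMSO libraries correlated with replicates 1 and 2 of sAKZ692 at 0.972 to 0.976 and with replicate 3 at 0.959 to 0.960. Replicate 3 was thus no closer to replicates 1 and 2 than the DMSO libraries were. The first principal component, with 62.7% of the variance, separated the treatments, and the second, with 23.6%, separated replicate 3 from replicates 1 and 2. Without replicate 3, 3163 genes were higher and 1321 lower, including 2193 of the 2204 and 776 of the 777 called with it. Of the 439 genes called without it and changed by at least 1 on the log2 scale, 412 (93.8%) moved the same way in replicate 3. Across all tested genes its change from DMSO correlated with that of replicates 1 and 2 at r = 0.63. Both changes share the DMSO mean.

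**Figure D1:**
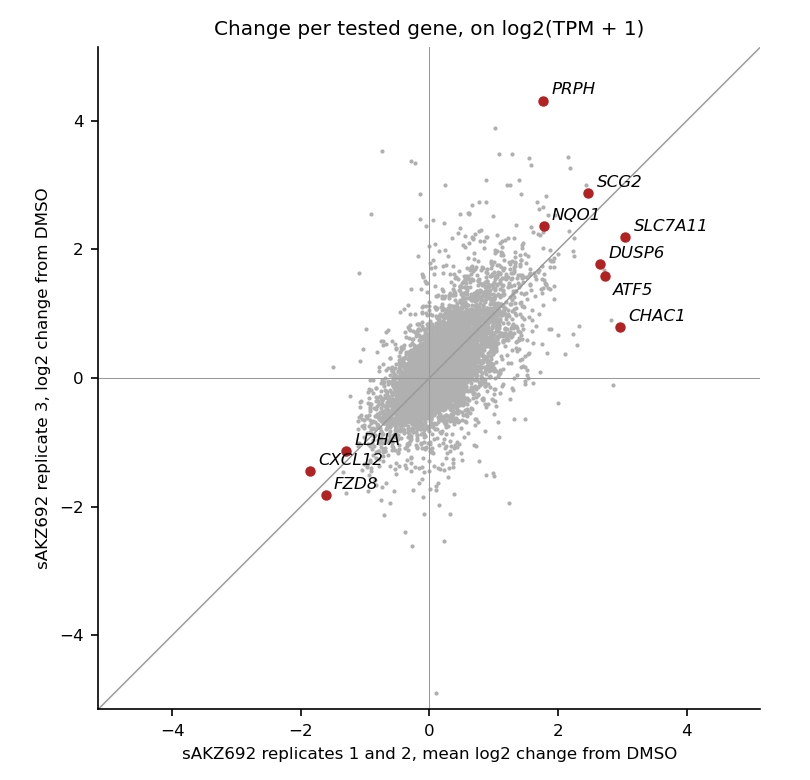
Change from the DMSO mean on log2(TPM + 1) of each of the 9137 tested genes (grey points) in replicates 1 and 2 of sAKZ692 (x axis, mean) and in replicate 3 (y axis), with 10 named genes in red and the diagonal marking equal change. SCG2 and NQO1 lie in the upper right near the diagonal, PRPH lies above it and CHAC1 below it.

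Most of the NRF2 target genes tested, 17 of 23, were higher with sAKZ692. NQO1, a quinone reductase and a standard readout of NRF2, rose from 15.7 ± 0.303 to 65.9 ± 16.9 TPM (SD, n = 3), a log2 fold change of 1.97 with a standard error of 0.16 and an adjusted p of 0.00051. PIR, a pirin gene under NRF2 control, rose from 39.3 ± 1.20 to 78.6 ± 1.74 TPM, and SRXN1, the sulfiredoxin that repairs oxidised peroxiredoxins, from 15.6 ± 1.21 to 34.3 ± 3.29 TPM. GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, rose from 24.8 ± 4.14 to 38.8 ± 3.42 TPM. TXNRD1, thioredoxin reductase 1, rose from 172 ± 7.64 to 291 ± 78.6 TPM, with treated libraries at 245, 246 and 382 TPM, and this call was lost without DMSO replicate 2 or 3 (adjusted p = 0.0537 and 0.0651). Of the 23 tested members, 17 were higher, 0 lower and 6 not past the threshold. Adjusted over the list alone, 19 were higher and 0 lower. Without replicate 3 of sAKZ692, 19 were higher and 1, TXN, lower (named after its value was seen). Without any 1 DMSO library, 12 to 14 were higher and 0 lower. The fixed NRF2 list held 40 genes, of which 24 had values.

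The median log2 fold change of the NRF2 list was 0.69, and 0.51 after median-ratio scaling, where 15 members were higher and 2 lower. Camera placed the list above the other genes with an adjusted p of 4.2e-05. That call was lost with an estimated correlation (adjusted p = 0.13). Leaving out any 1 library kept camera's adjusted p between 2.0e-05 and 5.6e-05.

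**Figure D2:**
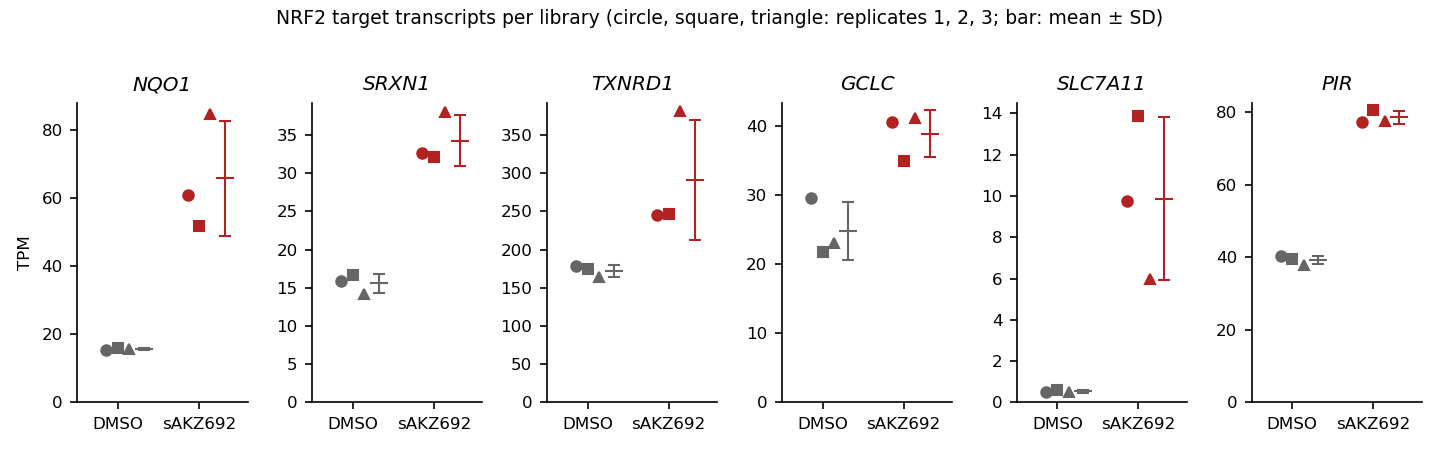
TPM of 6 NRF2 target genes in each library, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). The treated libraries lie above the DMSO libraries in each panel, and replicate 3 of sAKZ692 is the highest for NQO1, SRXN1, TXNRD1 and GCLC and the lowest for SLC7A11.

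In the list of the integrated stress response, which ATF4 drives, 17 of 23 genes were higher. ATF5 rose from 13.4 ± 0.877 to 77.2 ± 31.1 TPM (SD, n = 3), TRIB3, a pseudokinase induced by ATF4, from 3.46 ± 0.632 to 13.5 ± 2.64 TPM, and SARS, the cytosolic seryl-tRNA synthetase, from 214 ± 3.85 to 339 ± 28.7 TPM. Of these tested members, which include SLC7A11, 0 were lower and 6 not past the threshold, with 18 higher and 0 lower adjusted over the list alone. The median log2 fold change was 0.71 (camera adjusted p = 1.9e-05), with an adjusted p of 0.55 with an estimated correlation. This group moved with the library that stood apart. ATF5 was at 88.1, 101 and 42.2 TPM in the treated libraries, and without replicate 3 all 23 members were higher and the median was 0.93. Without any 1 DMSO library, 11 or 12 were higher.

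In the list of the ER unfolded protein response, SYVN1, an ER-associated ubiquitin ligase, rose from 22.8 ± 0.668 to 36.3 ± 1.98 TPM and HYOU1, an ER chaperone, from 95.8 ± 3.86 to 136 ± 11.4 TPM (SD, n = 3). HERPUD1 rose by 1.04 on the log2 scale, a call lost without any 1 library except replicate 3 (adjusted p up to 0.104) and after median-ratio scaling or quantile normalization (adjusted p = 0.054 and 0.051). Of 11 members, 3 were higher, 0 lower and 8 not past the threshold, 3 higher also adjusted over the list alone, and camera did not place the list apart (adjusted p = 0.50). Without replicate 3, 9 were higher and the list passed (adjusted p = 0.0025).

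Every tested gene of DNA replication fell. PCNA, the sliding clamp, fell from 332 ± 8.25 to 174 ± 12.7 TPM (SD, n = 3), and MCM7 and MCM2, subunits of the replicative helicase, fell from 594 ± 9.11 to 301 ± 31.0 TPM and from 158 ± 4.12 to 89.4 ± 7.47 TPM. TYMS, thymidylate synthase, fell from 395 ± 9.98 to 207 ± 20.8 TPM. All 14 tested members were lower, also adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 1.6e-14). With an estimated correlation the adjusted p was 0.096. After median-ratio scaling the median was -1.07 with 14 lower, and after quantile normalization 13 were lower.

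In the list of mitosis, 11 of 17 genes were lower. CCNA2, cyclin A2, fell from 84.5 ± 2.61 to 44.8 ± 8.02 TPM, the cell-cycle kinase CDK1 from 114 ± 2.60 to 64.1 ± 7.24 TPM, BIRC5, survivin, from 254 ± 5.74 to 148 ± 11.7 TPM, and the checkpoint kinase BUB1B from 34.9 ± 0.785 to 22.9 ± 2.31 TPM (SD, n = 3). Of the members, 0 were higher and 6 not past the threshold, and 15 were lower adjusted over the list alone. The median was -0.60 (camera adjusted p = 6.0e-11), with an adjusted p of 0.28 with an estimated correlation. Without replicate 3 all 17 were lower, and without any 1 DMSO library 7 or 8 were.

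**Figure D3:**
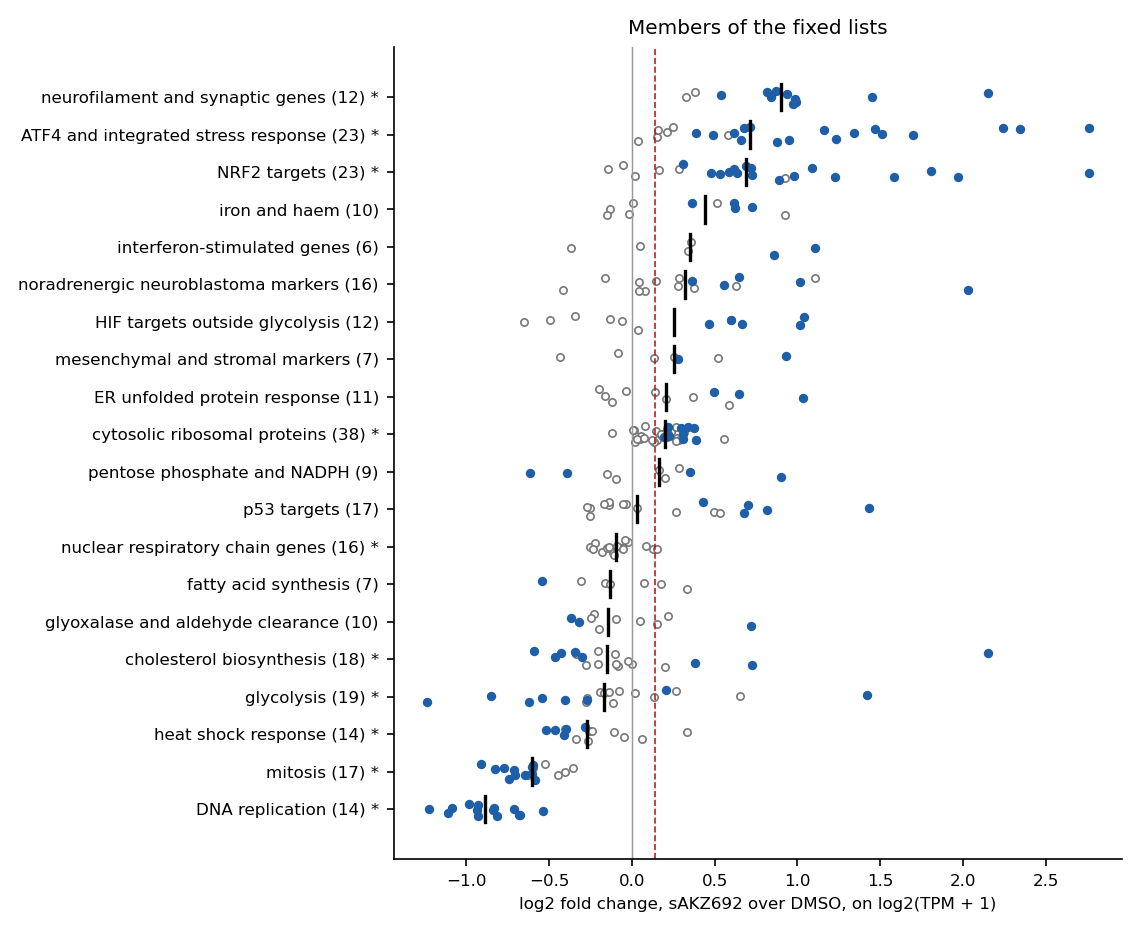
Log2 fold change on log2(TPM + 1) of each tested member of the 20 lists tested (x axis), with the number of members in brackets. Filled points passed the adjusted p threshold, open points did not, black bars are list medians, the dashed red line is the median of all tested genes at 0.14, and an asterisk marks lists past camera's threshold with the preset correlation. Medians run from -0.89 for DNA replication to 0.90 for neurofilament and synaptic genes, and the ribosomal protein median of 0.20 falls to 0.02 after median-ratio scaling.

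In glycolysis, several enzymes of the lower part of the pathway fell while the neuronal enolase rose. Beside LDHA, the pyruvate kinase gene PKM fell from 1322 ± 22.6 to 860 ± 26.1 TPM, ENO1 from 1302 ± 17.7 to 892 ± 36.1 TPM and PGAM1, phosphoglycerate mutase, from 416 ± 12.3 to 231 ± 33.7 TPM (SD, n = 3). ENO2, the neuronal enolase, rose from 33.3 ± 3.51 to 91.8 ± 20.5 TPM. PGK1, the phosphoglycerate kinase, had a log2 fold change of -0.27, lost without DMSO replicate 1 or 2 (adjusted p = 0.0760 and 0.0647) and after quantile normalization (adjusted p = 0.39). TPI1, triosephosphate isomerase, had one of -0.40, lost without any 1 library except replicate 3 (adjusted p up to 0.0775). GAPDH was at 6168 ± 57.5 TPM with DMSO and 5952 ± 1474 TPM with sAKZ692 and did not pass (adjusted p = 0.73), with treated libraries at 5143, 5061 and 7653 TPM and a log2 fold change of -0.27 without replicate 3 (adjusted p = 0.00030).

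Of 19 glycolysis members, 2 were higher, 6 lower and 11 not past the threshold, or 4 higher and 7 lower adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.00068). The call was lost with an estimated correlation (adjusted p = 0.096) and after quantile normalization (adjusted p = 0.064). Without replicate 3, 4 were higher and 9 lower, without any 1 DMSO library 1 was higher and 4 or 5 lower, and after median-ratio scaling 1 was higher and 10 lower.

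Lists next to glycolysis did not stand apart from the other genes in camera. Of 9 genes of the pentose phosphate pathway and NADPH supply, 2 were higher and 2 lower, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.61). The mitochondrial malic enzyme gene ME3 was at 1.40 ± 0.346 and 3.51 ± 1.04 TPM and the transhydrogenase gene NNT at 32.6 ± 1.21 and 41.8 ± 1.02 TPM with DMSO and sAKZ692, the folate enzyme gene MTHFD1 at 183 ± 10.5 and 120 ± 18.5 TPM and the ribose-5-phosphate isomerase gene RPIA at 43.6 ± 1.80 and 33.1 ± 2.11 TPM (SD, n = 3). Some of these calls were lost without a single library. That of ME3 was lost without DMSO replicate 2 or 3 (adjusted p = 0.0616 and 0.0540). That of NNT was lost without DMSO replicate 1 (0.0505) and that of RPIA without DMSO replicate 2 (0.0521). The log2 fold changes stayed near those with all libraries, at 0.79 and 0.91 against 0.90 for ME3, 0.33 against 0.35 for NNT and -0.36 against -0.39 for RPIA. Median-ratio scaling ended the call of NNT (0.12) and quantile normalization that of ME3 (0.12). The list's median was 0.16 and its mean 0.07, while camera's direction was down relative to the other genes. After median-ratio scaling the median was -0.02 with 1 higher and 3 lower, and without replicate 3 the median was 0.0087 with 4 higher and 2 lower. Without any 1 DMSO library 1 was higher and 1 or 2 lower.

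Of 10 genes of glyoxalase and aldehyde clearance, the aldehyde dehydrogenase gene ALDH2 was higher (69.4 ± 1.22 against 116 ± 16.6 TPM; SD, n = 3) and PARK7, the DJ-1 gene, lower (254 ± 5.84 against 203 ± 3.66 TPM), as was ALDH7A1, whose call was lost without any 1 library except replicate 3 (adjusted p up to 0.0870). Adjusted over the list alone, 1 was higher and 2 lower (camera adjusted p = 0.11). After median-ratio scaling 1 was higher and 6 lower, and without replicate 3 of sAKZ692 2 were higher and 5 lower. Of 12 HIF targets outside glycolysis, 5 were higher and 0 lower on either adjustment, among them NDRG1 (3.38 ± 0.349 against 8.04 ± 1.31 TPM) and the angiogenic factor VEGFA (6.11 ± 0.650 against 13.6 ± 3.34 TPM), but the list did not pass (camera adjusted p = 0.76), and its median of 0.25 turned to -0.02 after quantile normalization. After either scaling 2 were higher and 1 lower, and without any 1 DMSO library 2 or 3 were higher. MXI1 and PPFIA4, 2 more of the 5, lost their calls after median-ratio scaling (adjusted p = 0.084 and 0.059), after quantile normalization (0.060 and 0.31) and without single libraries, MXI1 without DMSO replicate 2 or 3 (up to 0.0974) and PPFIA4 without replicate 1 or 2 of either group (up to 0.0845). Of 3 glucose-responsive MondoA targets, too few for a set test, KLF10 and HBP1 had log2 fold changes of 0.34 and 0.41 and KLF11 of -0.53, and the calls of the first 2 were lost under both scalings (adjusted p between 0.091 and 0.39) and without any 1 DMSO library (up to 0.120 and 0.0668), that of KLF10 also with no filter on low values (0.0502) and without replicate 1 or 2 and that of HBP1 without replicate 2 of sAKZ692, and that of KLF11 without DMSO replicate 1 or 2 (adjusted p = 0.0619 and 0.0509).

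Of 16 nuclear genes of the respiratory chain, 0 passed limma's threshold, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. The median log2 fold change of these genes was -0.10 (camera adjusted p = 0.0099), with an adjusted p of 0.13 with an estimated correlation and of 0.032 in fry. After median-ratio scaling 8 were lower, with a median of -0.28 (camera adjusted p = 0.00080). Under quantile normalization the median was -0.01 and the call was lost (adjusted p = 0.86), and without replicate 3, 6 members were lower. The most abundant member, ATP5B, was at 934 ± 23.6 and 1058 ± 259 TPM, and COX5A at 373 ± 15.9 and 336 ± 10.9 TPM with DMSO and sAKZ692 (SD, n = 3). No mitochondrially encoded gene was analysed here.

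Of the neurofilament and synaptic genes, 10 of 12 were higher. NEFL and NEFM, the light and medium neurofilament chains, rose from 12.5 ± 1.09 to 35.8 ± 3.92 TPM and from 28.2 ± 1.56 to 56.7 ± 0.594 TPM (SD, n = 3). The synaptic vesicle genes SYP, synaptophysin, and VAMP2, synaptobrevin 2, rose from 54.3 ± 1.18 to 108 ± 6.88 TPM and from 23.7 ± 0.195 to 43.2 ± 3.38 TPM. Of the members, 0 were lower and 2 not past the threshold, and 12 were higher adjusted over the list alone. The median was 0.90, and 0.72 after median-ratio scaling (camera adjusted p = 5.8e-06 as deposited), with an adjusted p of 0.096 with an estimated correlation.

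Among 16 noradrenergic neuroblastoma markers, 5 were higher and 0 lower on either adjustment, and the list did not pass (camera adjusted p = 0.32), though it did after quantile normalization (adjusted p = 0.015). The median of 0.32 was 0.14 after median-ratio scaling, where 3 were higher and 2 lower, and 0.18 without replicate 3, where 7 were higher and 1 lower, and without any 1 DMSO library 2 or 3 were higher. GAP43, a growth cone protein, rose from 2.12 ± 0.291 to 12.6 ± 6.27 TPM, CHGB, chromogranin B, from 26.3 ± 0.977 to 54.7 ± 8.21 TPM and the neuronal RNA-binding protein gene ELAVL4 from 250 ± 12.6 to 372 ± 63.9 TPM (SD, n = 3), the last lost without DMSO replicate 3 (adjusted p = 0.0540). Of 7 mesenchymal and stromal markers, 2 were higher and 0 lower on either adjustment (camera adjusted p = 0.76). After median-ratio scaling 1 was higher and 1 lower, without replicate 3, 2 were higher and 2 lower, and without any 1 DMSO library 1 was higher. The 2 as deposited were PDGFRB, from 3.98 ± 0.467 to 8.50 ± 0.908 TPM, and THY1, at 67.3 ± 2.98 and 81.9 ± 4.23 TPM, whose call was lost without any 1 DMSO library (adjusted p up to 0.10) and after median-ratio scaling (adjusted p = 0.34).

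In the list of the heat shock response, 5 of 14 genes were lower and 9 did not pass the threshold. DNAJB1 and DNAJA1, co-chaperones of HSP70, fell from 129 ± 7.48 to 90.1 ± 4.66 TPM and from 321 ± 0.981 to 232 ± 5.91 TPM (SD, n = 3). The HSP90 co-chaperone genes STIP1 and AHSA1 had log2 fold changes of -0.40 and -0.41, the first lost without DMSO replicate 2 or 3 (adjusted p = 0.0537 and 0.0544) and the second without DMSO replicate 1 (adjusted p = 0.0523) and after quantile normalization (adjusted p = 0.13). Of 14 members, 0 were higher and 5 lower on either adjustment, with a median of -0.27 (camera adjusted p = 6.2e-05), and an adjusted p of 0.096 with an estimated correlation. Without replicate 3, 9 were lower, after median-ratio scaling 10, and without any 1 DMSO library 3.

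In cholesterol biosynthesis, members moved in both directions. IDI1, an enzyme of the mevalonate pathway, fell by 0.59 on the log2 scale and FDPS, another, from 321 ± 12.1 to 233 ± 11.5 TPM, while the sterol reductase gene TM7SF2 rose from 6.68 ± 0.969 to 33.6 ± 8.59 TPM and STARD4, a cholesterol carrier, from 32.8 ± 1.78 to 55.0 ± 1.10 TPM (SD, n = 3). Of 18 members, 3 were higher and 5 lower, or 3 and 6 adjusted over the list alone. The median was -0.15 while the mean was 1.3e-05, and camera's call (adjusted p = 0.011) was lost with an estimated correlation (adjusted p = 0.27) and after quantile normalization (adjusted p = 0.21). Fry's test of a move on balance one way did not pass either (adjusted p = 0.17). Its test of change in either direction did (adjusted p = 4.7e-05). After median-ratio scaling 2 were higher and 8 lower. Without replicate 3, 8 were lower, and without any 1 DMSO library 3 or 4. Of 7 genes of fatty acid synthesis, 1 was lower and 0 higher on either adjustment (camera adjusted p = 0.12). This was ACLY, the ATP citrate lyase, which fell from 517 ± 30.7 to 355 ± 24.5 TPM. After median-ratio scaling 4 of the 7 were lower, and without replicate 3, 2 were higher and 2 lower.

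Of 38 cytosolic ribosomal protein genes, whose reads can be shared with pseudogenes, 9 were higher and 0 lower, or 6 and 0 adjusted over the list alone, with a median of 0.20 that was 0.02 after median-ratio scaling, where 0 were higher and 1 lower. RPL5 was at 1607 ± 18.3 and 2104 ± 61.2 TPM and RPL3 at 1805 ± 14.4 and 2280 ± 110 TPM with DMSO and sAKZ692 (SD, n = 3), and median-ratio scaling ended both calls (adjusted p = 0.060 and 0.17). Those of RPL4 and RPL23 ended as well (adjusted p = 0.25 and 0.17), that of RPL4 also after quantile normalization (adjusted p = 0.10), and leaving out any 1 DMSO library ended those of RPL4 and RPL23 (adjusted p up to 0.0809 and 0.0806) and leaving out DMSO replicate 1 that of RPL3 (adjusted p = 0.0562). Camera's adjusted p of 0.030 became 0.75 after median-ratio scaling and 0.60 with an estimated correlation, and the list also lost its call without DMSO replicate 1 or 2 or replicate 1 of sAKZ692 (adjusted p up to 0.16), with no filter on low values (0.084) and in limma without the trend (0.090). Without any 1 DMSO library 1 to 3 were higher, and without replicate 3 of sAKZ692, 22 were higher and 1 lower.

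Of 10 genes of iron and haem, 4 were higher and 0 lower, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.40). The ferrochelatase gene FECH rose from 20.5 ± 1.26 to 32.1 ± 3.10 TPM (SD, n = 3) and HEBP1 by 0.73 on the log2 scale. FTH1, the ferritin heavy chain, was at 3065, 3124 and 4954 TPM in the treated libraries against 2363 ± 50.7 TPM with DMSO. Its call was lost without any 1 DMSO library (adjusted p up to 0.103), after median-ratio scaling (adjusted p = 0.11) and with no filter on low values (adjusted p = 0.0505). That of IREB2 was lost without any 1 DMSO library (adjusted p up to 0.0738) and after median-ratio scaling (adjusted p = 0.14), and also without replicate 2 of sAKZ692 and after quantile normalization (adjusted p = 0.053). After median-ratio scaling 2 were higher and 1 lower. Without any 1 DMSO library 2 of the 10 were higher, and without replicate 3, 6.

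Of 17 p53 targets, 5 were higher and 0 lower on either adjustment, and the list did not pass (camera adjusted p = 0.95), with a median of 0.03 that turned to -0.15 after median-ratio scaling, where 4 were higher and 4 lower. Without replicate 3, 7 were higher and 6 lower. BBC3, the PUMA gene, rose from 3.38 ± 0.357 to 11.5 ± 5.48 TPM, the death receptor gene TNFRSF10B from 70.1 ± 3.08 to 114 ± 19.0 TPM and TP53INP1 from 7.45 ± 0.182 to 13.9 ± 1.29 TPM (SD, n = 3). ZMAT3 rose from 4.46 ± 0.241 to 7.86 ± 0.138 TPM and missed the threshold narrowly after quantile normalization (adjusted p = 0.0501). Of 6 interferon-stimulated genes, IFI6 and ISG15 were higher and the other 4 not past the threshold, on either adjustment (camera adjusted p = 0.39), with IFI6 at 7.15 ± 0.538 and 16.8 ± 3.96 TPM and ISG15 at 2.26 ± 0.412 and 4.92 ± 0.821 TPM, the latter lost after quantile normalization (adjusted p = 0.089).

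The remaining lists had fewer than 5 tested members. TIPARP, the single AhR target tested, had a log2 fold change of 0.45, lost without any 1 library except replicate 3 (adjusted p up to 0.127), under both scalings (adjusted p = 0.13 and 0.58) and with no filter on low values (adjusted p = 0.056). MT1X, the single metallothionein gene tested, did not pass (adjusted p = 0.17). Of 4 immediate early genes, KLF4 was lower (-0.76) and the other 3 not past the threshold, and of 4 NF-kB targets, TNFAIP2 was higher (0.98) and the other 3 were not. Both of those calls were lost without any 1 DMSO library (adjusted p up to 0.114 and 0.112), that of KLF4 also without replicate 1 or 2 and that of TNFAIP2 without replicate 2 of sAKZ692, and that of TNFAIP2 after quantile normalization (adjusted p = 0.14). The 2 genes with the highest mean TPM were GAPDH and DDX1, a helicase gene co-amplified with MYCN. DDX1 was at 7736 ± 162 TPM with DMSO and 6307 ± 290 TPM with sAKZ692 (SD, n = 3; adjusted p = 0.024), a call lost without any 1 library except replicate 3 (adjusted p up to 0.0984), after quantile normalization (adjusted p = 0.44) and with no filter on low values (adjusted p = 0.095).

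Of the 20 lists tested, 10 passed camera's threshold with the preset correlation, 4 higher and 6 lower than the other genes, and 0 of the 10 passed with an estimated correlation, where the unadjusted p of 6 lay under 0.05.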

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

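Limma array weights and the restriction to protein-coding genes were chosen only after the data had been seen. The counts of 2204 higher and 777 lower genes became 1242 and 1754 after median-ratio scaling, 1077 and 1184 after quantile normalization, and 392 and 23 with a log2 fold change of at least 1 also required. With array weights 3267 and 1324 were called, the weight of replicate 3 of sAKZ692 being 0.156 and the others above 1. Leaving out 1 library gave 1213 to 3163 higher and 404 to 1321 lower genes, with the highest values without replicate 3 of sAKZ692 and the lowest without a DMSO library. The cause was not tested, except that a stricter threshold lowers a count by construction. The settings not named here kept both counts within 1.5 times. In fry 15 lists passed. Among them, not past camera's threshold, were glyoxalase and aldehyde clearance, lower, and HIF targets outside glycolysis, higher (fry adjusted p = 0.0081 each). Iron and haem (0.00089), interferon-stimulated genes (0.0038) and noradrenergic neuroblastoma markers (0.015) also passed only in fry, all higher. Of the 10 lists past camera's threshold, 0 passed with an estimated correlation. There the NRF2 median stayed at 0.69 but camera's adjusted p rose to 0.132, against 6.1e-09 to 0.00015 in the other camera settings. Fry, which tests for a move on balance one way without comparing with other genes, gave the NRF2 list an adjusted p of 0.00089. The iron and haem list had the same value in fry. The pentose phosphate and NADPH list, with a median of 0.162, lay below the other genes in camera and above 0 in fry (adjusted p = 0.028), since fry does not compare a list with other genes.

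Of the 104 named genes, 68 kept their side of the threshold in each setting that gave a value. Of the 100 called ones 0 changed sign, while ATP5B and GAPDH, which were not called, changed sign in some settings. Without 1 library, 31 of the called ones lost the call at least once. Median-ratio scaling ended 15 calls, quantile normalization 16, the absence of a filter on low values 4 and limma without the trend 1. Of the other 19 lists, 3 kept their side of the threshold in each setting, those of fatty acid synthesis, mesenchymal and stromal markers and p53 targets, and none of these had passed it. The medians of the p53, HIF and pentose phosphate lists, also not past it, changed sign in some settings. A minimum mean of 5 TPM left 9 named genes and 1 list without a value. The count-based test among the alternatives was not run. With the replicate number as a block, 1863 genes were higher and 636 lower, and the calls of DDX1, KLF10, KLF4, PPFIA4, THY1 and TIPARP ended, 6 of the named ones. Deviations of same-numbered libraries from their group means correlated at 0.061, -0.025 and 0.042 for numbers 1, 2 and 3. Numbers 1 and 3 but not 2 correlated best with their own number. The check gave no clear sign of pairing. It cannot exclude pairing, because replicate 3 of sAKZ692 stood apart and weighs on every deviation in its group. Depth is unknown, so the precision of low genes cannot be judged from counts.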

Other observations

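The 3 gene lists in the first paragraphs, the tests of replicate 3, both tests of scaling on the excess of higher genes and the intervals on the steps between low levels were chosen only after the results had been seen. DUSP6, induced by ERK signaling, was higher with sAKZ692, and ETV4, also induced by it, was higher in replicates 1 and 2 (41.4 and 53.5 TPM) but not in replicate 3 (8.21 TPM, against 11.1 ± 2.24 TPM with DMSO; SD, n = 3), and these 2 prompted a list of 20 further ERK feedback and target genes without them. Of its 11 tested members, 7 were higher, 0 lower and 4 not past limma's threshold, and 9 were higher without replicate 3 of sAKZ692. SPRED3, an inhibitor of the ERK cascade, rose from 2.10 ± 0.298 to 9.69 ± 2.10 TPM (SD, n = 3), and the transcription factor genes ETV1 and ETV5 rose from 4.79 ± 0.342 to 12.2 ± 2.69 TPM and from 15.4 ± 2.37 to 37.6 ± 15.4 TPM. CCND1, the cyclin D1 gene, was at 185 ± 9.25 and 200.3 ± 49.1 TPM with DMSO and sAKZ692 and did not pass. These genes were named after their values were seen. The median log2 fold change of the list was 0.85, and 0.70 after median-ratio scaling and 0.45 after quantile normalization. Camera gave an adjusted p of 0.0064, but with an estimated correlation the unadjusted p was 0.33, so that these genes may rise together with the compound remains a hypothesis.

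A list of 24 lysosome genes, 18 of them tested, had 14 members higher, 1 lower and 3 not past the threshold. GRN, the progranulin gene, rose from 243 ± 8.06 to 415 ± 15.5 TPM, PSAP, the prosaposin gene, from 207 ± 12.6 to 355 ± 14.7 TPM and GAA, the acid alpha-glucosidase gene, from 46.5 ± 0.695 to 82.0 ± 3.82 TPM (SD, n = 3), while the protease gene CTSL fell from 85.2 ± 2.06 to 65.6 ± 6.60 TPM. These too were named after their values were seen. The median was 0.45, and 0.27 after median-ratio scaling, where 6 members were higher and 1 lower. Camera gave an adjusted p of 0.00024 and the unadjusted p with an estimated correlation was 0.060, so a joint rise of lysosome genes also remains a hypothesis. Since the list was chosen after the results had been seen, these p-values are not independent support for it. A list of retinoic acid targets, prompted by CRABP2 and STRA6, had only 2 tested members, too few for a set test. RARG was at 10.9 ± 1.07 and 15.6 ± 1.14 TPM (limma adjusted p = 0.014) and HOXC4 at 40.0 ± 1.53 and 55.0 ± 12.7 TPM (adjusted p = 0.059).

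In replicate 3 of sAKZ692, 334 genes differed at least 2-fold from the mean of replicates 1 and 2, against 44 between those 2, among them, named after their values were seen, CRABP2 (175, 146 and 19.6 TPM in replicates 1, 2 and 3, and 21.3 ± 2.86 with DMSO), ASS1 (827, 983 and 155 TPM, and 452 ± 50.0) and EPB41L3 (9.24, 8.17 and 50.3 TPM, and 8.48 ± 1.86). Library-wide scaling is argued against, since after quantile normalization the SD over genes of the difference was still 2.24 times that expected from replicates 1 and 2. A weaker response as the whole cause is argued against, since in 76.9% of the 334 genes replicate 3 lay outside the span from DMSO to the other replicates by more than 2 SD of DMSO. The binomial 95% interval of 72.1 to 81.4 is over genes, which are not independent, within this 1 library. RNA of cells without the MYCN amplicon is argued against in the large share that the 18 genes at least 4-fold lower in replicate 3 would need. The ratios of MYCN, DDX1 and NBAS to the other replicates were 1.12, 0.92 and 1.22, with a median of 1.12. A small share of such RNA was not tested. A different passage or subline of the same cells could give such values and stays open, as the labels record neither, and no other biological explanation was tested.

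More genes were higher than lower with sAKZ692. The excess was largest in the low tertile of tested genes by mean TPM, which reached up to 10.5 TPM, with 902 higher and 52 lower. In the high tertile, from 36.2 TPM, 521 were higher and 556 lower. One scaling factor per library stays open for the excess over all genes, where median-ratio scaling (41.5% of the calls higher) decides nothing because it sets the median gene near 0, but is argued against for the gap between tertiles, since their median log2 ratios differed by 0.45 (bootstrap 95% interval over genes 0.42 to 0.48). This interval and those of the steps below resample genes, which are not independent, and do not measure the spread between libraries. By library, the gap was 0.45, 0.50 and 0.37 in replicates 1, 2 and 3 of sAKZ692 and between -0.04 and 0.05 in the DMSO libraries. Transcript length is argued against as the whole cause of that gap, because its smallest value in any quintile of length was 0.40. Background reads added to each transcript may contribute. Of the 2017 genes of 0.1 to 1 TPM, which lay under the filter and were not tested, 78.1% had a higher mean TPM with sAKZ692. The median log2 ratio went from 0.18 at 10 to 30 TPM to 0.64 at 0.3 to 1 TPM. It then went by a step of -0.07 (interval -0.16 to 0.03) to 0.1 to 0.3 TPM. A further step of -0.19 (interval -0.35 to -0.04) led to 0.38 in the 197 genes under 0.1 TPM, of which 69.5% had a higher mean. By the rule fixed before this result was seen, the lack of a climb below 1 TPM counted against such reads. The share of genes with a higher mean also missed the rule's minimum for them. The interval of the first step, added afterwards, spans no change. The last step goes against such reads but lies near the floor and in genes picked by a low mean over both groups. Background reads therefore stay open, as does, untested, a broad rise of weakly transcribed genes with the compound.

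The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 of the 10, the real split, gave the highest value in each case. It called 2981 genes against 0 in the highest of the others, placed 10 lists past camera's threshold against 7, and gave the NRF2 targets a median of 0.69 against 0.34 in size. Each of the other splits had treated and DMSO libraries in both groups. This widens the spread within groups and leaves part of the treatment difference between them, so few gene calls there were built into the design. Those splits still placed 4 to 7 lists past camera's threshold at the preset correlation while calling 0 genes.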
